A study of Mus musculus with 2 samples.

How the data were processed

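Polyadenylated RNA was sequenced from the central nervous system of C57BL/6J mouse embryos at day 11.5, as strand-specific paired-end libraries. Per the labels, each of the 2 libraries came from mixed-sex littermates and the libraries are biological replicates 1 and 2 of 1 tissue. The labels describe no dissection boundary, and the linked protocols were not used here. With 1 group there was no contrast between groups, so no test between conditions was run and no p-value is given. With n = 2, an SD measures only the spread between these samples.

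The gene and transcript tables of each library lie on mm10 with annotation release M4, per the notes deposited with the files. The aligner and the quantifier are not given in the sources used here. The authors deposited an expected count per gene, which need not be a whole number, together with TPM and FPKM, per the file headers. The deposited TPM sums over all rows, spike-ins included. The deposited transcript tables also give each transcript's percent of its gene. That column was not used, and shares were recomputed from transcript TPM. For the whole series the authors deposited mm9 gene tables with RPKM values for both replicates, 1 on Ensembl 65 gene models and 1 on models assembled by Cufflinks, per the file headers. No label ties the first or second RPKM value to replicate 1 or 2, so they are called the first and second mm9 value and means were used for agreement with mm10. A deposited mm9 junction list gives the read count over each junction from each replicate, again without a link to a sample, and a deposited score. A deposited mm9 contig list gives a coverage level pooled over both replicates and a score. The 2 scores were not used. Exon tables and mm9 transcript tables were not used here.

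Each gene table held 69691 rows: 43346 Ensembl genes, 26248 rows with numeric identifiers, 96 ERCC spike-ins and 1 phiX174 row. Symbols and gene types were taken from GENCODE M21 by identifier without version, and 42462 of the 43346 genes matched. Coordinates are mm10 positions from that annotation. The rows with numeric identifiers held 44 expected counts in replicate 1 and 3 in replicate 2 and, like the spike-ins, stayed out of library sizes. Total expected counts were 126358800 and 111687581. Fold intervals are exact 95% binomial intervals on the read counts of the 2 libraries. They cover counting error only, and compare these libraries, not conditions.

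Expected counts were rounded to whole numbers. Libraries were scaled by TMM in edgeR 4.0.16, with DESeq2 1.42.0 size factors as an alternative, and the common dispersion was estimated in edgeR with an intercept only. Log2 ratios are replicate 2 over replicate 1 with a prior count of 0.5. A gene was said to differ between the libraries when its counts summed to at least 100 and its log2 ratio was at least 1 in size. Where a library had a count of 0, the fold was computed against a floor of 3 counts in that library. It is a lower bound that allows for counting error only. The median log2 ratio of 15037 genes with a mean CPM of at least 1 was -0.00 under TMM, -0.04 under DESeq2 size factors and 0.12 for log2(TPM + 1). Positions of contigs and junctions were compared with mm9 gene spans in bedtools 2.31.1 and pandas 2.3.3 under Python 3.11.15.

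Gene lists, the rule for named genes and the main set of alternative settings were fixed before the data were examined. The 32 lists held 411 genes, of which 406 matched 1 gene row each and 38 stood in more than 1 list. Ahsp, Rmst, Sox2ot and Snhg1 had no matching symbol, and Dlx6os1 matched 2 rows and was left out. The level of a list is the median of its members' mean TPM, with the SD of the medians of the 2 libraries. The shift of a list is the median log2 ratio of its members with a mean CPM of at least 1, given as its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. The rule named, for each list, the 3 members with the highest mean TPM and the lowest member, 14 genes fixed in advance, the 10 nuclear genes with the highest mean TPM, the 5 genes with the largest ratio each way, and the 3 highest and 3 lowest major isoform shares of a list of 30 genes. Some genes that this rule names are not reported here. Other genes named below were chosen after their values were seen. Lists for caudal neurons, limb bud, somite, heart and tail bud were written after the main data were seen and before the values of their own genes were, except for 6 of the 37 genes, which stood in earlier lists.

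Bounds for each test of an explanation were written down with the test. An explanation was counted as argued against only where a value passed its bound by more than the spread, taken as 0.5 times the distance between the quartiles of the members, or as the 95% Wilson interval of a share. This margin was not part of the bounds first written. It was brought in after the value of the caudal neuron list had been seen, at first for 2 of the 7 tests only, and was then applied to all 7 alike. Without it, a mixture of caudal neural tissue with trunk mesoderm would also have been argued against, and so would a trend with GC content by the bound of 0.5 first set. A comparison of that trend with the size of the mitochondrial change was added after both values had been seen.

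The scripts were tested on simulated data. Counts were drawn for the real genes at the real library sizes with 200 genes changed. In the tests of the size rule and of lists, the draws held counting error only. For replicate 2 over replicate 1, the size rule recovered 61% of genes changed 2-fold among 16515 genes, 98% of those changed 4-fold among 16488 and 96.5% of those changed 8-fold among 16516. It called 1, 0 and 0 unchanged genes. A simulated list of 15 genes raised 1.5-fold among 15037 genes lay above all random lists, and 4.5% of 200 unchanged lists fell outside the 2.5 to 97.5 percentiles. Without variation between libraries beyond counting error, these draws do not give the rate of false calls in the real libraries. Simulated biological coefficients of variation of 0.1 and 0.3 over 18462 genes were recovered as 0.0992 and 0.297.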

Results

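The 2 libraries describe the messenger RNA of the mouse central nervous system at embryonic day 11.5, a stage at which the neural tube holds dividing progenitors beside newly formed neurons. Replicate 1 held 126358800 expected counts and replicate 2 held 111687581. Ensembl genes carried 95.3% and 96.7% of them. The description below covers which genes the tissue expressed and how far the 2 libraries differed.

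In both libraries 14241 genes reached a TPM of at least 1, among them 13047 of 21474 protein-coding genes, 181 of 2777 long intergenic noncoding RNA genes and 324 of 5349 processed pseudogenes. The nuclear gene with the highest level was Hbb-y, an embryonic beta globin, at 11303 ± 3625 TPM (SD, n = 2, as for all values below given with ±). It was followed by the noncoding Gm42418 at 9553 ± 3401, the translation factor Eef1a1 at 8965 ± 217, Ptma at 6098 ± 3014 and the alpha globin Hba-a2 at 5134 ± 1574. Rps12 (5006 ± 1123), Rplp1 (4869 ± 1863), Hba-a1 (4562 ± 944), the pseudogene Gm29216 (4388 ± 3089) and the alpha tubulin Tuba1a (3919 ± 285) completed the 10 highest. The adult-type globin copies are near-identical, so their separate values are uncertain. Whether reads of the pseudogene Gm29216 came from a near-identical sequence elsewhere was not tested.

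Genes of neural progenitors, neurogenesis and young neurons were expressed together. All 18 measured progenitor genes reached 1 TPM in both libraries, with a list median of 71.8 ± 8.79 TPM. The intermediate filament gene Vim stood at 1898 ± 1053 TPM, the lipid carrier Fabp7 at 520 ± 63.6, Dbi at 403 ± 15.7 and Lin28b, the lowest, at 10.2 ± 0.141. The transcription factor gene Sox2 stood at 73.9 ± 24.9 TPM, Pax6 at 60.1 and 43.1 in replicates 1 and 2, and the filament gene Nes at 153 ± 114. Of 18 genes of neurogenic commitment 17 reached 1 TPM in both, led by Gadd45g (221 ± 168), Hes6 (173 ± 57.7) and the Notch ligand Dll1 (86.3 ± 28.7), while Neurog3 stood at 1.01 ± 1.05. All 20 genes of postmitotic neurons were present, with a median of 52.6 ± 0.714 TPM: Tubb3 (neuronal tubulin) at 801 ± 114, Gap43 at 252 ± 90.4, Stmn3 at 226 ± 122, Map2 at 112 ± 11.1, Dcx at 53.0 ± 6.89 and Myt1l, the lowest, at 4.36 ± 0.410. All 20 proliferation genes were present at a median of 145 ± 21.4 TPM, from Pcna (405 ± 17.2), Top2a (334 ± 97.1) and Cdk1 (332 ± 30.5) down to Bub1 (41.6 ± 9.89).

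Genes of mature synapses and of glia had lower list medians than those of progenitors and young neurons. Of 16 synapse genes 12 reached 1 TPM in both libraries, with a median of 2.70 ± 0.0672 TPM. Dlg4 (79.4 ± 14.4) and Gria2 (18.1 ± 1.03) were among the highest and the receptor subunit Grin2a lowest (0.21 TPM in each library). In the astrocyte list, which also holds early radial glia genes, 8 of 12 passed. Fgfr3 (91.4 ± 16.7), Sox9 (51.3 ± 7.16) and Gja1 (50.3 ± 17.1) led it, whereas Gfap stood at 0.410 ± 0.113 and Aqp4 at 0.290 ± 0.113. Of 12 oligodendrocyte lineage genes 9 passed. Several also stand in other lists, Pdgfra in mesenchyme, Sox10 in neural crest, and Olig2 and Nkx2-2 in the ventral neural tube. Their presence does not show this lineage by itself. Pdgfra (34.6 ± 22.8) and Cnp (10.5 ± 2.43) were among the highest, Olig2 stood at 8.14 ± 2.42, and the myelin gene Mog was listed at 0 in both.

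The list medians of transmitter genes were 10.3 TPM for glutamatergic, 10.5 for inhibitory, 2.36 for cholinergic (1.28 in replicate 1 and 3.67 in replicate 2) and 5.49 for monoaminergic neurons. For glutamatergic neurons 6 of 8 genes reached 1 TPM in both, among them Lhx9 at 34.9 ± 8.35, Barhl2 at 19.6 ± 9.67 and the vesicular transporter Slc17a6 at 12.6 ± 0.467, with Grin2b at 0.475 ± 0.177. For inhibitory neurons 11 of 12 passed, with Lhx1 at 26.7 ± 1.70, the GABA-synthesising enzyme Gad1 at 22.8 ± 7.86 and Dlx1 at 18.3 ± 1.92. The glycine transporter Slc6a5 was lowest, at 0.13 TPM in replicate 1 and 3.38 in replicate 2. Of 12 cholinergic motor neuron genes 7 passed. Isl1 (31.5 ± 6.70), Prph (19.5 ± 4.31) and Isl2 (14.3 ± 2.19) were highest and Chat lowest (0.515 ± 0.643). Of 13 monoaminergic genes 7 passed, led by Lmx1b (17.5 ± 11.9), Ddc (12.2 ± 2.93) and Gata2 (10.8 ± 0.778), with the dopamine transporter Slc6a3 at 0.145 ± 0.0212.

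Regional genes covered the forebrain, the midbrain and both poles of the dorsoventral axis. Of 18 forebrain genes 17 passed, with a median of 17.0 ± 4.57 TPM, Lhx2 at 125 ± 43.2, Tcf7l2 at 79.0 ± 0.820, Otx2 at 67.6 ± 27.2 and Rax at 1.20 ± 0.933. Of 16 midbrain and isthmus genes 15 passed, with Meis2 at 77.1 ± 39.7, En2 at 29.7 ± 21.7 and Tal2 at 29.1 ± 12.1. Pitx3, the lowest, stood at 0.09 TPM in replicate 1 and 3.19 in replicate 2. In the dorsal list 15 of 16 passed, led by Zic1 (166 ± 61.8), Msx1 (47.6 ± 5.90) and Zic2 (36.3 ± 4.27), with Ptf1a at 1.33 ± 0.0990. In the ventral list 14 of 16 passed, led by Dbx1 (44.4 ± 22.5), Gli1 (25.2 ± 8.77) and Ptch1 (24.8 ± 7.08), with Dbx2 at 0.385 ± 0.00707. The hindbrain list had 8 of 12 and a median of 4.13 ± 2.41 TPM, from medians of 1.61 TPM in replicate 1 and 5.02 in replicate 2. Its highest members were Hoxb3, Hoxb2 and Hoxa3 and its lowest Egr2 (0.39 and 0.41 TPM in replicates 1 and 2).

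Genes of blood, vessels, connective tissue and other organs were present beside the neural genes. All 13 measured erythroid genes passed, down to Gata1 at 8.68 ± 1.45 TPM, and the embryonic globin Hbb-bh1 stood at 2169 ± 641. All 12 endothelial genes passed, with Egfl7 at 112 ± 28.9, Cldn5 at 29.3 ± 6.38, Cdh5 at 24.3 ± 7.04 and Flt1 at 3.98 ± 0.643. All 14 mesenchyme and meninges genes passed, from Col3a1 (264 ± 34.4), Col1a2 (160 ± 11.2) and Col1a1 (119 ± 37.9) to Foxc2 (8.11 ± 4.12). Macrophage genes passed in 11 of 12 cases, with Tyrobp at 18.1 ± 5.55, C1qb at 17.8 ± 0.976, Fcer1g at 12.9 ± 2.63 and P2ry12 at 0.935 ± 0.346. Liver and yolk sac genes passed in 10 of 12, with Afp at 238 ± 96.6, Alb at 231 ± 172, Ttr at 89.0 ± 61.2 and Cubn at 0.17 and 0.23 in replicates 1 and 2. Surface epithelium genes passed in 10 of 12, from Krt8 (11.5 ± 1.40), Krt18 (10.7 ± 0.354) and Epcam (8.21 ± 1.47) to Grhl2 (0.925 ± 0.658). Of 13 neural crest and ganglion genes 11 passed, with Isl1 highest, Ngfr at 25.2 ± 11.2 and Tfap2b at 24.5 ± 0.403. Of 12 muscle, cartilage and heart genes 7 passed, with Actc1 at 237 ± 191, Col2a1 at 190 ± 10.8, Tnnt2 at 115 ± 44.8 and Tbx6 at 1.14 ± 0.191. Eye and pituitary genes passed in 6 of 12, from Cryab (7.43 ± 4.41), Pomc (6.70 ± 3.15) and Lhx3 (3.06 ± 2.21) to Crygs (0.0250 ± 0.00707).

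Imprinted genes formed a high list, with 15 of 16 passing and a median of 292 ± 18.8 TPM. H19 stood at 2169 ± 947, Nnat at 1475 ± 511, Meg3 at 1474 ± 172 and Kcnq1ot1 at 1.27 ± 0.431. Of 12 long noncoding RNA genes 11 passed, with Gas5 at 1258 ± 81.4 and Xist, from the pooled sexes, at 283 ± 111. All 15 splicing regulators passed, with Ptbp1 at 243 ± 140 above Ptbp2 at 117 ± 18.4, Khdrbs1 at 107 ± 4.48 and the neuronal Rbfox3 lowest at 5.94 ± 0.354. All 12 reference genes passed, including Eef1a1, Tuba1a, Gapdh (3605 ± 53.4) and Hprt (41.3 ± 3.42).

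**Figure D1:**
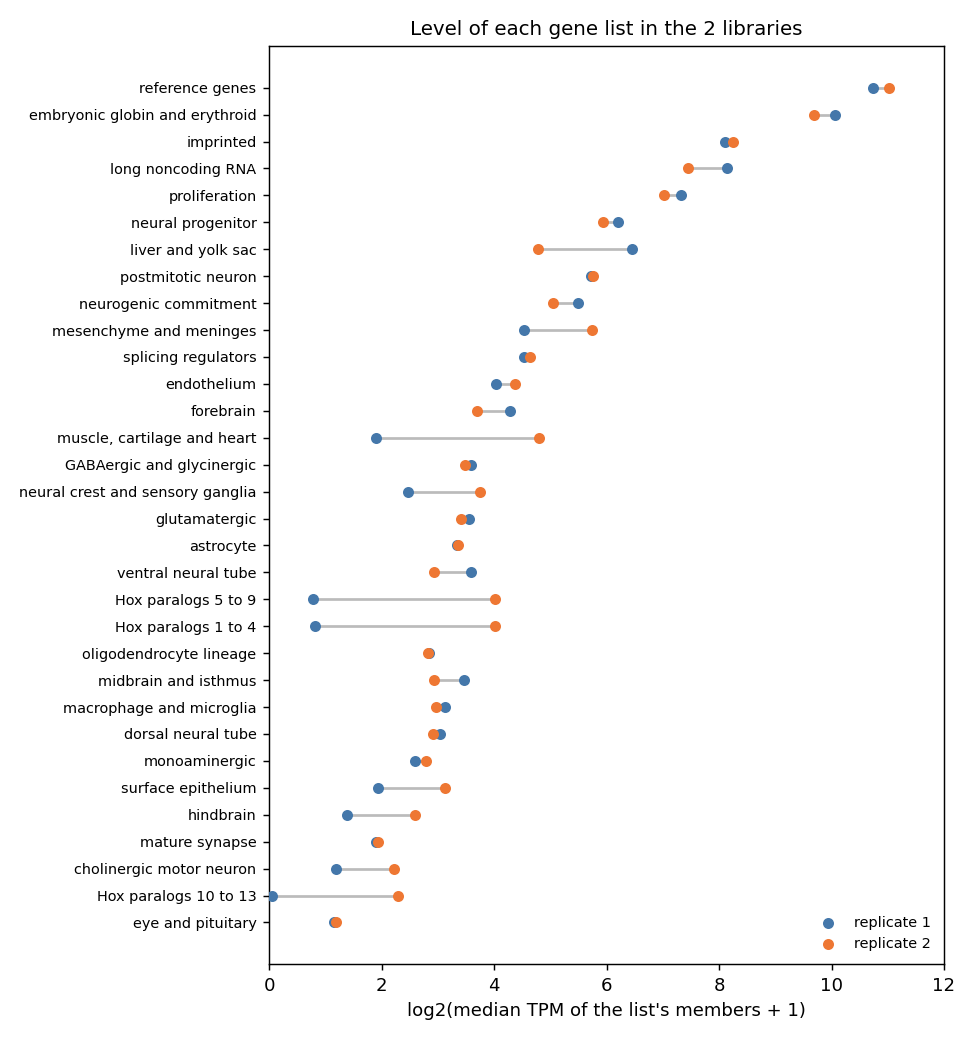
Median TPM over the members of each of the 32 gene lists, as log2(median TPM + 1), with 1 point for each library and a line joining them. Progenitor, proliferation and postmitotic neuron lists lie close together in the 2 libraries, whereas the Hox lists lie near 0 in replicate 1 and apart from it in replicate 2 (medians of 0.72 and 15.1 TPM for paralogs 5 to 9).

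Hox genes, which mark the hindbrain, spinal cord and trunk along the body axis, separated the 2 libraries. Over 12 genes of paralog groups 1 to 4 the median was 0.76 TPM in replicate 1 and 15.1 in replicate 2. Over 15 genes of groups 5 to 9 it was 0.72 and 15.1, and over 12 genes of groups 10 to 13 it was 0.035 and 3.92. In replicate 1 no member of groups 10 to 13 reached 1 TPM, against 9 in replicate 2. Hoxb9 (chromosome 11, 96271457 to 96276595) had 34 counts in replicate 1 and 4876 in replicate 2, a scaled fold of 148 (106 to 214). The highest members of their groups were also higher in replicate 2: Hoxb3 18.2-fold, Hoxd3 43.4-fold and Hoxd4 47.7-fold, then Hoxc6 26.6-fold, Hoxa9 40.9-fold and Hoxa5 16.6-fold, then Hoxa10 52.0-fold, Hoxc10 102-fold and Hoxd10 75.3-fold. The lowest members were Hoxb1 (0.14 and 0.71 TPM), Hoxc9 (0.10 and 5.34) and Hoxb13 (0 and 0.07).

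The median log2 ratios of the 3 Hox lists were 3.89, 4.66 and 6.64, each above all 10000 random lists matched on mean expression. With the 2 members at 0 counts in replicate 1 set to their lower bound, the last median was still 6.64. Every measured member, 10 of 10, 15 of 15 and 9 of 9, was at least 2-fold higher in replicate 2.

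**Figure D2:**
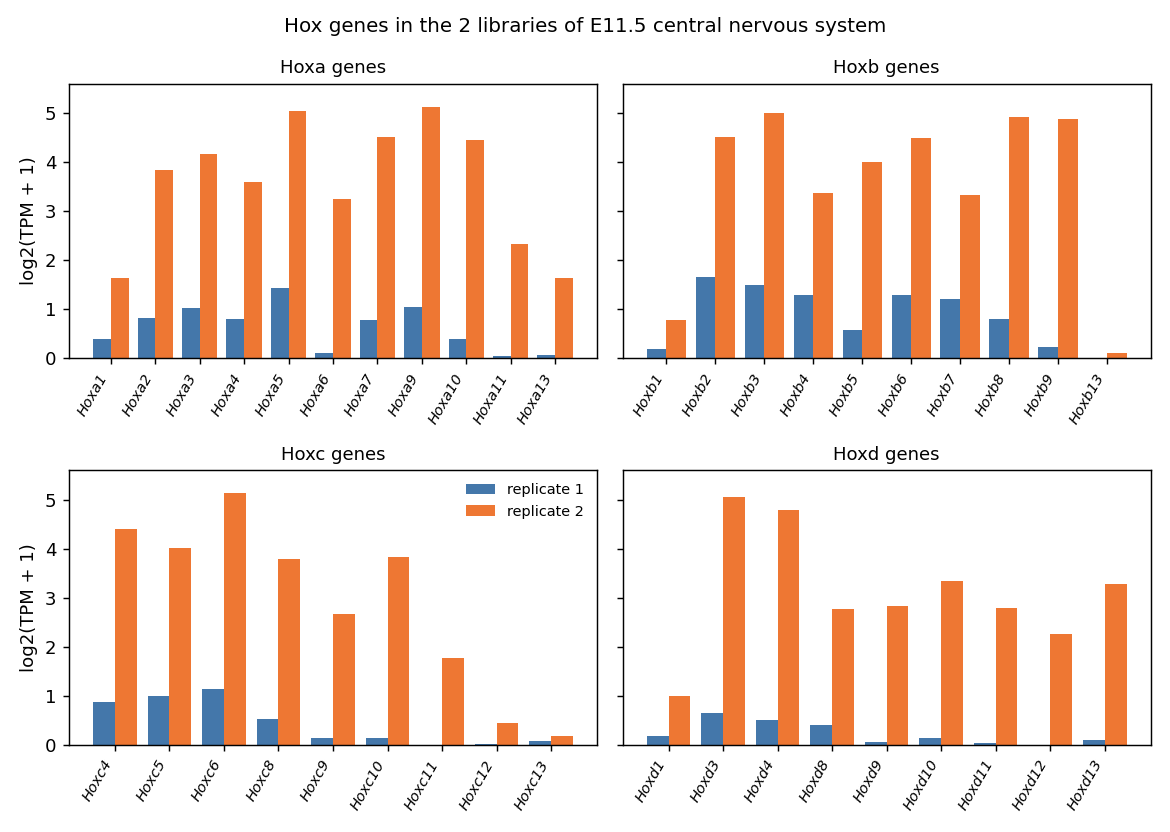
Level of 39 Hox genes as log2(TPM + 1) in replicate 1 (blue) and replicate 2 (orange), in the order of their paralog numbers within each of the 4 clusters. Every gene is higher in replicate 2, where Hoxc6 reaches 34.1 TPM, while the highest value in replicate 1 is 2.13 TPM, of Hoxb2.

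Myogenic regulator genes were also higher in replicate 2. The myogenic regulators Myod1 (chromosome 7, 46376474 to 46379099), Myog and Myf5 stood at 0.15, 0.40 and 0.10 TPM in replicate 1 and at 19.4, 34.2 and 2.87 in replicate 2. Pax1, a sclerotome gene, stood at 0.63 and 15.8 TPM. The muscle, cartilage and heart list had a median log2 ratio of 1.49, above all random lists, with 7 of 12 members at least 2-fold higher, though Tnnt2, Nppa and Col2a1 had ratios of -0.98, -0.36 and -0.37. The hindbrain list (1.65, 5 of 10 at least 2-fold higher), the cholinergic motor neuron list (0.86, percentile 99.9), neural crest and sensory ganglia (0.69, percentile 99.96, with Sox10 3.81-fold and Erbb3 6.78-fold higher) and mesenchyme (0.67, above all random lists, with Prrx1 3.29-fold higher) also lay above the central range. The hindbrain list shares its Hox members with the list of groups 1 to 4. Imprinted genes (0.49) lay above all random lists, with 11 of 16 members above 0 and Igf2, Peg10 and Mest 2.47-, 2.40- and 2.16-fold higher, while Cdkn1c, Zrsr1 and Ndn had ratios of -0.64, -0.61 and -0.54. The erythroid list (0.39, percentile 99.9) had 7 of 13 members above 0, Hbb-bs was 2.15-fold lower, and on the log2(TPM + 1) scale its median was 0.11 and inside the range of random lists.

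Lists of the forebrain, the midbrain, the dorsal and ventral neural tube and neurogenesis were lower in replicate 2. All 18 forebrain genes had a negative log2 ratio, with a median of -0.77 that lay below all random lists, and 7 were at least 2-fold lower, among them Six3 (3.01-fold) and Rax (3.90-fold). Neurogenic commitment (-0.87), the ventral neural tube (-0.84), the dorsal neural tube (-0.63) and the midbrain (-0.48, percentile 0.05) were also lower. En2 was 3.56-fold lower, Gadd45g 3.82-fold and Dll3 3.02-fold. Members went both ways in the midbrain list, where 4 of 16 were above 0 and Pax2 and Pax8 were 3.18- and 3.20-fold higher, and in the ventral list, where 5 of 15 were above 0. In scaled counts the dorsal list held 1 exception, Lbx1, at 0.05 TPM in replicate 1 and 2.94 in replicate 2. In TPM, Zic1 (122.6 and 209.9) and Tlx3 (7.48 and 8.26) were also higher in replicate 2. The dorsal median on the log2(TPM + 1) scale was -0.42. Progenitor genes had a median of -0.39 (percentile 1.12), with Nes (chromosome 3, 87971078 to 87980451) 3.71-fold (3.66 to 3.76) lower and Hmga2 3.06-fold higher. Postmitotic neuron genes (-0.35, percentile 1.84) and glutamatergic genes (-0.40, percentile 2.26) lay just below the range. On the log2(TPM + 1) scale the postmitotic neuron median was -0.21 and inside the range of random lists. Liver and yolk sac genes were lowest of all lists at -1.56, with 8 of 11 at least 2-fold lower, including Alb (3.67-fold) and Apoa1 (4.32-fold).

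In all, 19 of the 32 lists lay outside the central 95% of random lists, 10 above and 9 below. The other 13 lay inside it, among them proliferation (-0.32), mature synapse (0.05), endothelium (0.20), macrophage (-0.12), inhibitory neurons (-0.12), monoaminergic (-0.14), oligodendrocyte lineage (0.27), astrocyte (0.25), surface epithelium (0.43), eye and pituitary (-0.03), long noncoding RNA (0.02), splicing regulators (0.14) and reference genes (0.10). These ratios have 1 library on each side and no replicate check. Members of random lists were drawn independently, so their range does not allow for genes that vary together. Since 38 genes stand in more than 1 list, the 19 lists are not separate results.

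**Figure D3:**
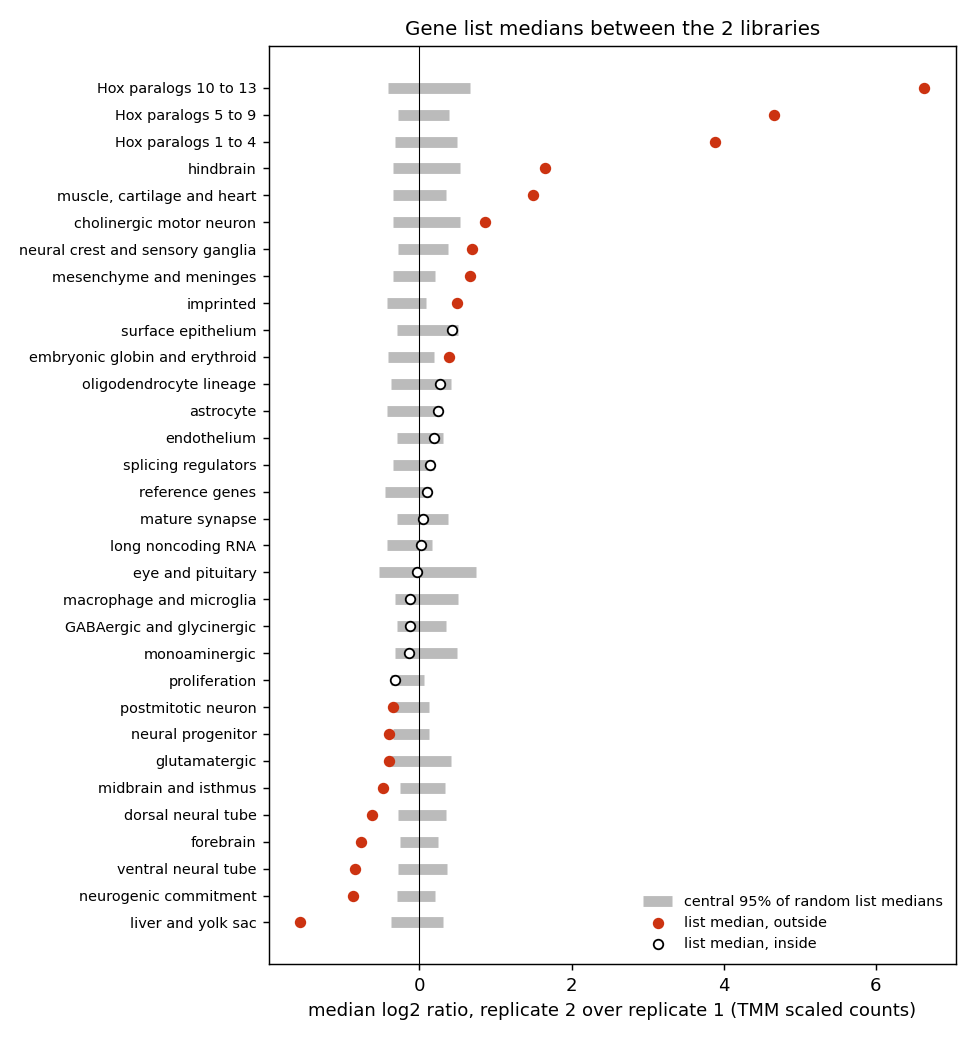
Median log2 ratio, replicate 2 over replicate 1, of each gene list (points) against the central 95% of medians of random lists matched on mean expression (grey bars). Filled points mark the 19 lists outside their bar, from liver and yolk sac at -1.56 to Hox groups 10 to 13 at 6.64.

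Across all genes the libraries were similar in rank and apart for many single genes. Pearson's r of log2(TPM + 1) was 0.976 and Spearman's rho 0.961 over 24771 genes, which are not independent replicates. Of the 14241 genes above 1 TPM in both, 90.4% lay within 2-fold, and the SD of the log2 ratio was 0.644. The biological coefficient of variation was 0.331 over 18462 genes. Of 16511 genes with at least 100 counts, 1075 were at least 2-fold higher in replicate 2 and 818 lower. Pseudogenes differed often. Of 354 processed pseudogenes 185 differed (52.3%), 162 of them lower in replicate 2, and of 27 unprocessed pseudogenes 15 differed (55.6%), 13 of them higher, whereas 1417 of 14757 protein-coding genes differed (9.60%).

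The 5 largest ratios toward replicate 2 were all of genes with 0 counts in replicate 1. They were the processed pseudogene Gm15387 (chromosome 15, 74093686 to 74094333; 13162 counts, at least 4520-fold higher), Rsc1a1 (908 counts, at least 312-fold), Hoxd12 (655 counts, at least 225-fold), Trpc2 (596 counts, at least 205-fold) and Gm27998 (381 counts, at least 131-fold). Rsc1a1, Trpc2 and Gm27998 overlap another gene on the same strand, so their reads may not be separable. The 5 largest ratios the other way had 0 counts in replicate 2. These were the histone gene Hist1h4m (646 counts, at least 209-fold lower), the pseudogene Rpl7a-ps11 (360 counts, at least 116-fold), Gm11632 (254 counts, at least 82.2-fold) and 2 genes without a symbol, ENSMUSG00000103316.1 (2378 counts) and ENSMUSG00000103565.1 (380 counts). Histone H4 genes have near-identical copies, and Gm11632 overlaps Fbxl20, so these values are uncertain. Gm15387 and Rpl7a-ps11 are processed pseudogenes, so their 0 counts may depend on how reads were split among copies. That was not tested for them, and their lower bounds do not allow for it.

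Mitochondrial genes and spike-ins also took different shares of the libraries. Mitochondrial genes carried 0.683% of expected counts in replicate 1 and 2.09% in replicate 2, and 1.35% and 6.78% of TPM. The short gene mt-Atp8 stood at 1340 and 30725 TPM, while in scaled counts it was 13.3-fold (12.8 to 13.7) higher in replicate 2. Whether reads of mitochondrial genes were shared with near-identical nuclear sequences was not tested, and these shares and folds do not allow for it. ERCC spike-ins carried 5.51% ± 1.74 of TPM (SD, n = 2), with 80 and 82 of the 96 detected, 79 of them in both. The 55 spike-ins with at least 100 counts in each library had a median log2 TPM ratio of -0.66 and a Spearman correlation of 0.990. The nominal amounts of the spike-ins were not used here.

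Most genes kept the same major transcript in both libraries. Among 8768 genes at 10 TPM or more in both, 7373 (84.1%) had the same most abundant transcript. For the 6597 of these with several annotated transcripts it was 78.9%, and the median share of the major transcript was 64.5%. In a list of 30 neural and splicing-regulated genes, 27 passed the level and 15 kept their major transcript. Shares were highest for Ptbp2, which has a single annotated transcript, Mapt (Mapt-204, 93.5% ± 0.649) and Pkm (Pkm-201, 89.7% ± 1.09). They were lowest for Meis2, Pax6 and Tcf7l2, whose major transcripts differed between the libraries at shares of 23.4% and 20.3%, 19.7% and 25.4%, and 34.3% and 19.5%.

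The mm9 tables describe the same libraries through another set of gene models. Over 33068 shared genes the mean mm9 RPKM and the mean mm10 TPM had a Spearman correlation of 0.946. On mm9, 34 of 34 Hox genes with a value above 0.1 were higher in the second mm9 value, with medians of 0.0612 and 1.52 RPKM. The junction list held 1270088 junctions and 129997260 reads, and 278645 junctions had reads in both replicates. A single read supported 60.7% of the junctions. The junction with the most reads lay in Hbb-y (mm9 chromosome 7, 111000517 to 111001261; 392454 reads). The 816060 contigs covered 698 Mb counted over both strands, and 58.9% of them (95% Wilson interval 58.8% to 59.1%) overlapped an Ensembl 65 gene on the same strand, with 83.3% of the covered length. That interval treats contigs as independent and measures no spread between libraries. A further 10.8% overlapped a gene on the opposite strand only, and 30.3% overlapped none.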

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

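The mm9 table of gene models assembled by Cufflinks was used in no comparison above. It held 166608 models, of which 52720 overlapped no Ensembl 65 gene on either strand. Of these, 198 had an RPKM of at least 1 in both replicate values, with medians of 4.04 and 2.46 RPKM. This signal stands out because it lies outside the Ensembl 65 genes on mm9. It was not compared with the mm10 genes, on which most other values rest. The highest lay on chromosome 1 at 24621720 to 24623065, minus strand, at 333 and 953 RPKM, and the next on chromosome 9 at 110183748 to 110183915, plus strand, at 578 and 304 RPKM. The first lay on the same chromosome and strand as Gm29216 (mm10 24615706 to 24616197), but whether they were the same gene was not tested.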

How the results depend on the processing

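The alternatives without Hox, mitochondrial and processed pseudogene genes, with protein-coding genes only and with lists matched also on GC were chosen after seeing the data. The count of expressed genes ranged from 10817 at a threshold of 5 TPM to 15678 at 0.5, the number of list genes detected from 260 to 374 of 406 in TPM (224 with mm9 values, in RPKM), and the number of lists outside the random range from 17 to 20. With single replicates, 14641 to 15170 genes were expressed and 334 to 374 list genes. Single lists kept their direction and their place inside or outside the random range in 118 of 128 comparisons, and no list outside the range changed direction. Of 7 changes of direction, the only one that left the range was the oligodendrocyte list, which turned from 0.27 to -0.51 without the expression filter. The others, all inside the range, were the eye and pituitary list (0.0424) without the filter, long noncoding RNA (-0.00748) with DESeq2 size factors, and on the TPM scale the monoaminergic (0.0562), macrophage (0.10), eye and pituitary (0.16) and long noncoding RNA (-0.19) lists. The postmitotic neuron and erythroid lists came inside the random range on the TPM scale, and surface epithelium fell outside it with lists matched also on GC. List levels moved by more than the spread between libraries in 60 of 160 comparisons, 28 of them with mm9 values, which are in another unit. Pearson's r was 0.971 with a pseudocount of 0.1, 0.956 over genes above 1 TPM in both, 0.985 with TMM scaled CPM, and 0.979 without Hox genes, mitochondrial genes and processed pseudogenes. The coefficient of variation was 0.388 without a filter and 0.273 above 10 CPM, and the cause was not tested. Differing genes numbered 2987 of 19338 tested (1745 higher and 1242 lower in replicate 2) at a summed count of 20. They numbered 1893 of 16511 at 100 and 1115 of 13610 (584 and 531) at 500. The share that differed fell as the minimum count rose, so the number tested does not alone account for the change. Differing genes numbered 1417 of 14757 among protein-coding genes only. Genes sharing a major transcript numbered 12147 at 1 TPM, since more genes entered. The spike-in share was 3.23% of expected counts, the mm9 correlation 0.853 over genes above 1 in both, and the share of contigs in genes 58.5% when at least 50% of a contig had to overlap. With 1 library on each side, list shifts and differing genes could not be recomputed without a replicate. No paired analysis was possible because there is only 1 group.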

Other observations

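Lists added after the data were seen extend the difference between the libraries to further tissues. Limb bud genes had a median log2 ratio of 1.52, above all 10000 random lists, with Tbx4 at 0.44 TPM in replicate 1 and 6.82 in replicate 2, Tbx5 at 0.70 and 6.77 and Tbx15 at 3.47 and 15.9. Shox2, in the same list, was at 31.3 and 35.1 TPM. Somite genes had a median of 1.11 (percentile 99.99), with Pax9 at 0.25 and 7.51 TPM and Tcf15 at 4.12 and 11.8, against Uncx at 59.7 and 29.6. Heart genes had a median of -0.01 (percentile 47.9), with Myl2 at 127 and 122 TPM and Myl4 at 104 and 111. The tail bud list had too few measured members for a percentile; in it Nkx1-2 and Wnt3a were 2.11- and 2.73-fold lower in replicate 2 and Cdx2 stood at 0.05 and 0.15 TPM. Of the 37 genes in these lists, 6 also stood in a list described above, 3 of them in the caudal neuron list.

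Some junctions joined near-identical gene copies. A junction with 264837 reads joined Hba-a1 to Hba-a2 on mm9 chromosome 11 (32184129 to 32197079), close to the 264708 reads of the matching junction inside Hba-a2. Similar long junctions joined Hbb-bt to Hbb-bs (92088 reads) and Tuba1b to Tuba1a (80059 reads). These were the gene pairs among the 5 strongest junctions that carried a flag of 0 in the list, a flag whose meaning is not given in the sources used here.

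The tests in the next 3 paragraphs address differences between the libraries that had already been seen. The tests of mitochondrial counts and of GC content as the whole cause were chosen only after their results were seen, and so was the margin that a value had to pass beyond its bound. The labels give both libraries as the same tissue. For the Hox genes, 2 explanations by the tissue content of replicate 2 were tested, and none by that of replicate 1. No biological explanation was tested for the other patterns, nor was RNA quality.

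Hox genes were far higher in replicate 2. The mm10 quantification is argued against as the cause, because the 2 mm9 values of Hox genes differed by a median absolute log2 ratio of 4.44 (quartiles 3.83 and 5.35), and junction reads inside 38 Hox genes numbered 392 and 8575. A pseudocount of 0.01 RPKM was added to the mm9 values of Hox genes. Whether replicate 2 held trunk mesoderm without caudal neural tissue, or both together, stays open. The caudal neuron list had a median log2 ratio of 0.46 (percentile 93.9), just below the bound of 0.5 set beforehand. Its members went both ways, with 7 of 10 above 0 (quartiles -0.23 and 1.18). The list cannot decide the question, because some members were well expressed in replicate 1, where Hox genes were low. Prdm12 stood at 14.9 TPM there against 9.28 in replicate 2, and Dmrt3 at 6.03 against 3.99. Within the caudal neuron list Mnx1 and Skor1 were 2.94- and 3.22-fold higher and Prdm12 1.83-fold lower. The cholinergic motor neuron list, which shares Isl2 and Mnx1 with it, had a median of 0.86 (percentile 99.9). All 10 of its measured members were above 0, with Slc18a3 18.2-fold (12.2 to 28.5) and Lhx3 3.67-fold higher. Slc18a3 lies inside the Chat gene on the same strand, so their reads may not be separable. Outside both lists Slc6a5 was 23.7-fold higher (18.8 to 30.3) and Lbx1 50.9-fold higher (27.4 to 107). The inhibitory neuron and dorsal neural tube lists that hold these genes had medians of -0.12 and -0.63. Which tissue expressed Slc6a5 and Lbx1 was not tested. Not all mesenchyme genes moved with the limb and somite lists: Prrx1 was 3.29-fold higher, while the abundant collagens Col3a1, Col1a2 and Col1a1 went from 289, 168 and 146 TPM in replicate 1 to 240.1, 152 and 92.3 in replicate 2.

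Mitochondrial genes were higher in replicate 2. Short effective lengths that inflate TPM are argued against as the whole cause, because the 13 protein genes had a median log2 ratio of 2.00 (quartiles 1.27 and 2.77) in scaled counts, which do not use length. A trend with GC content is argued against as the whole cause too, because 915 nuclear genes in the same GC range (31.9% to 41.1%) had a median of 0.41 (quartiles 0.07 and 0.73), short of 2.00 by more than both spreads. A part of the change due to GC stays open, and sharing of reads with near-identical nuclear sequences was not tested. The members did not move alike, with mt-Atp6 at a ratio of 3.76 and mt-Nd6, the only protein gene on the minus strand, at -2.38.

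Processed pseudogenes were frequent among the differing genes. Short length is argued against as the whole cause, since 16.2% of 1157 protein-coding genes shorter than 1000 bases differed, against 52.3% (95% Wilson interval 47.1% to 57.4%) of the pseudogenes. Wilson intervals in this paragraph treat genes as independent and measure no spread between libraries. A different split of reads among near-identical copies may contribute: of 149 differing pseudogenes with mm9 values, 31.5% (24.6% to 39.4%) were also 2-fold apart there, against 48.6% of 1371 differing protein-coding genes. A pseudocount of 0.1 RPKM was added to these mm9 values, which shrinks ratios of low values. The pseudogenes and protein-coding genes were not matched on level, so level alone may lower the share. The share of pseudogenes lay between the limits set beforehand, so a split of reads among copies stays open.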
